A study of Mus musculus with 50 samples.

How the data were processed

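The series holds 50 Affymetrix mouse genome arrays of polysomal RNA from young adult mouse colon (YAMC) cells, 10 for each of the parental cells, the bleo/Neo vector population and the mp53, Ras and mp53/Ras populations, per the labels' protocols. Cells were kept at 39 °C without interferon gamma for 48 h and then for 24 h in medium with 0% serum, and 5 µg of RNA was labelled per array. The labels number the replicates but do not say whether replicates of a population were separate cultures or days, so the p values measure the spread between these samples only. Each population exists once, so differences between populations cannot be told from differences between independent derivations of a population.

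The authors deposited a single table of 1 intensity per probe set and array, on a linear scale. RMA is named in the submitters' processing notes, without a version, and nothing is stated about how the log scale was undone. The arrays have almost the same distribution, with the same lowest and highest value and medians from 86.4 to 86.7 on the linear scale, so the deposited intensities had been quantile-normalised across the 50 arrays. Of 45101 probe sets, 64 control probe sets were blank and 45037 had values. The table has no detection calls, scan dates or batches, so none could be examined. No read depth applies to arrays, and the number of arrays limits the precision.

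The intensities were transformed to log2 without an offset, the lowest value being 3.04 on that scale. Gene symbols came from the platform annotation, with the reference gene table (assembly GRCm38.p6) used for names only, and 34741 of the 34945 probe sets with exactly 1 symbol matched it by gene number. Probe sets with several symbols (932) or none (9160) were left out of the gene tests. Of the 18193 gene symbols, each represented by its probe set with the highest mean, 12883 had a value above the median of the whole table (6.44) on at least 10 of the 50 arrays and were tested. No coordinates are given, because no genome build is named for the table.

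All arrays entered a single limma fit (version 3.58.1, R 4.3.3) with 1 coefficient per group, moderated with an intensity trend, and Benjamini-Hochberg adjustment over the tested genes of each of 7 comparisons. A gene was called changed at an adjusted p under 0.05, and the number that also differed at least 2-fold is given beside it. The comparisons were mp53/Ras, mp53 and Ras against bleo/Neo, bleo/Neo against YAMC, mp53/Ras against mp53 and against Ras, and the non-additive term. A description on the linear scale counted genes changed in mp53/Ras against bleo/Neo whose summed mp53 and Ras levels were at most 0.9 of the mp53/Ras level, or whose mp53/Ras level was at most 0.9 of each. The correlation of mp53 and Ras differences was set beside 100 simulations and beside 100 divisions of the bleo/Neo arrays into sets of 5. Each simulation drew unchanged groups and a shared control, 10 arrays each, from the deviations of all 50 arrays from their group means.

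Gene lists, 25 in all, were fixed before the data were examined, as were the fit, the filters and the rule for naming genes. They cover p53 targets, MAPK feedback and ERK-induced genes, EGF family, cell cycle, type I interferon, interferon gamma and antigen presentation, chemokines and cytokines, extracellular matrix, matrix proteases, epithelial junctions and keratins, mesenchymal transition, glycolysis and hypoxia, cholesterol synthesis, unfolded protein and amino acid response, ribosomal proteins and translation, BCL2 family and death receptors, Notch, Wnt, Hox, and TGF-beta and BMP, and 1 list that was tested and counted with the others but is not described here. Markers of colon differentiation, fibroblasts and smooth muscle, endothelial and immune cells, and squamous and neural cells stood for other cell types. Some genes belong to more than 1 list, for example Fn1 and Sparc to the matrix and mesenchymal lists. Lists were tested with limma's camera with a preset inter-gene correlation of 0.01, called at an adjusted p under 0.05 over the lists, and tested again with an estimated correlation and with fry. Counts of members are also given adjusted over the list alone.

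Genes are named by a rule: among called genes whose 10 arrays of the higher group all lay above the 10 of the lower, the 10 largest rises and falls in mp53/Ras against bleo/Neo, 8 each for mp53 and Ras, and 5 each for the other comparisons. For the non-additive term the 8 largest of each sign that also changed in mp53/Ras were taken, without the rule on overlap. Up to 4 members of each called list, members moving against their list, and a few reference genes were added, and genes with predicted names only were passed over. Genes non-additive on both baselines, Xist and the Y-linked genes were chosen after seeing the data. Bright probe sets are those above the same filter. Another bright probe set of a called gene is given where it showed less than 0.4 of the named change or the opposite sign, a limit chosen after seeing the data.

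The alternatives were no filter, a stricter filter at the 60th percentile, quantile normalisation, centring on medians, no intensity trend, array weights, the replicate number as a block, the mean of all probe sets, leaving out probe sets that may match several transcripts, the fit of the compared groups alone, YAMC as the control, and a limit of 0.8 on the linear scale. Alternatives chosen after seeing the data left out 2 or 4 arrays that lie nearer another group, compared both oncogenes with YAMC, or asked for the same sign on both baselines. Correlations over arrays and their p values came from 100000 permutations, two-sided.

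The code was tested on simulated arrays made from the means and spreads of the 12883 genes, with 200 genes changed. For mp53/Ras against bleo/Neo, 86.6% of changes of 0.5 (log2), 98.5% of 1 and 100% of 2 were recovered, and 0.177% of unchanged genes were called. For mp53 against bleo/Neo the shares were 85.1%, 100% and 100%, and for the non-additive term 61.2%, 97% and 100%, with 0% of additive genes called. The list that was shifted in the simulation was called, and 0 other lists were. Genes were simulated independently, whereas members of real lists can be correlated (estimate 0.494 for type I interferon response). The simulation therefore does not show how often lists are called falsely in the real arrays. Tables were handled with the data.table package (version 1.17.8), and figures were drawn with matplotlib 3.10.9 under Python 3.11.15.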

Results

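Young adult mouse colon (YAMC) cells are an epithelial line kept dividing by a temperature-sensitive viral large T antigen, which is switched off at 39 °C without interferon gamma. Retroviruses carrying empty vectors (bleo/Neo), a mutant p53 (mp53), activated Ras (Ras) or both oncogenes (mp53/Ras) gave 4 polyclonal populations, which were studied beside the parental YAMC cells. Polysomal RNA, the mRNA bound to several ribosomes, was hybridised to Affymetrix mouse genome arrays after 48 h at 39 °C and 24 h without serum. There were 50 arrays, 10 in each of 5 groups, and 12883 genes were tested. Intensities from polysomal RNA depend on transcript abundance and on ribosome loading together. Differences are on the log2 scale with the standard error of the limma fit (±) and n = 10 arrays per group, and arrays give no read depth, so that their number limits the precision. Because the groups are of equal size, a gene has the same standard error with YAMC as with bleo/Neo as the control. Probe sets of the introduced oncogenes were not analysed here, so the transgenes themselves do not check the labels.

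Ras and mp53/Ras cells were the most alike of the 5 populations, with a root mean square difference of 0.268 between their mean profiles, and mp53 cells were about as close to YAMC cells (0.269). The widest distance was between bleo/Neo and mp53/Ras cells (0.594). The vector population bleo/Neo lay 0.429 from its parental cells, farther than mp53 cells did and about as far as Ras cells (0.421). The nearest group mean was the array's own for 46 of the 50 arrays. The array labelled mp53 10 lay nearer Ras, the array labelled Ras 10 nearer mp53, the array labelled YAMC 2 nearer mp53, and the array labelled mp53 8 nearer YAMC.

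**Figure D1:**
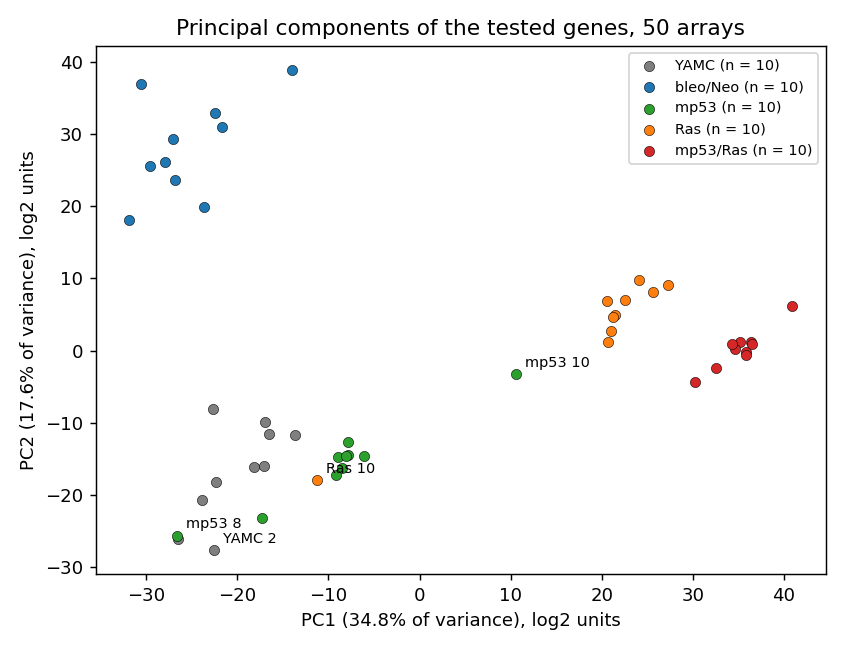
First and second principal components (34.8% and 17.6% of the variance, log2 units) of the 12883 tested genes for 50 arrays, coloured by group. The 10 bleo/Neo arrays lie apart from the YAMC arrays, Ras lies beside mp53/Ras, and the arrays labelled mp53 10 and Ras 10 lie away from the other arrays of their groups.

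The comparison of bleo/Neo with YAMC asks what vectors and drug selection did without an oncogene. Among the largest falls in bleo/Neo cells, Col1a2, a chain of type I collagen, fell by 4.62 ± 0.14, Bgn, the proteoglycan biglycan, fell by 4.28 ± 0.10, and Myl9, a myosin light chain of contractile cells, fell by 5.47 ± 0.28. The transcription factor gene Zic1 fell by 5.16 ± 0.20 and the ribosomal protein gene Rps4l fell by 5.77 ± 0.13. Higher in bleo/Neo were Gpm6a, a neuronal membrane glycoprotein (5.16 ± 0.21), and Ddx4, a germ-cell RNA helicase (4.17 ± 0.47). So were the potassium channel gene Kcnk1 (3.59 ± 0.20), the aldo-keto reductase gene Akr1c14 (3.49 ± 0.17) and Cldn15, a tight-junction claudin (3.33 ± 0.12). In total 4813 genes changed, 2576 higher and 2237 lower, of which 357 changed at least 2-fold (135 higher, 222 lower).

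The Y-linked genes Eif2s3y, Kdm5d and Uty also fell in bleo/Neo cells, by −4.65 ± 0.17, −3.14 ± 0.19 and −3.40 ± 0.19, and in all 10 bleo/Neo arrays they lay below the 40 other arrays. Their bleo/Neo levels of 3.73, 3.63 and 3.58, like that of Zic1 (3.64), lie near the lowest value of the table (3.04), where background limits the difference that can be measured, so these falls are lower bounds. The same holds for rises of these genes, and of Clca3a1 (3.87 in bleo/Neo), in the comparisons with bleo/Neo. Xist, the RNA that coats the inactive X chromosome, rose by 1.52 ± 0.25. Mean Xist levels were 8.04 in YAMC, 9.55 in bleo/Neo, 7.19 in mp53, 8.81 in Ras and 9.34 in mp53/Ras cells, and the mean of the 3 Y-linked genes was 7.38, 3.65, 7.89, 7.17 and 6.44 in the same order. Every comparison with bleo/Neo therefore also compares populations that differ in Y-linked transcripts.

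**Figure D2:**
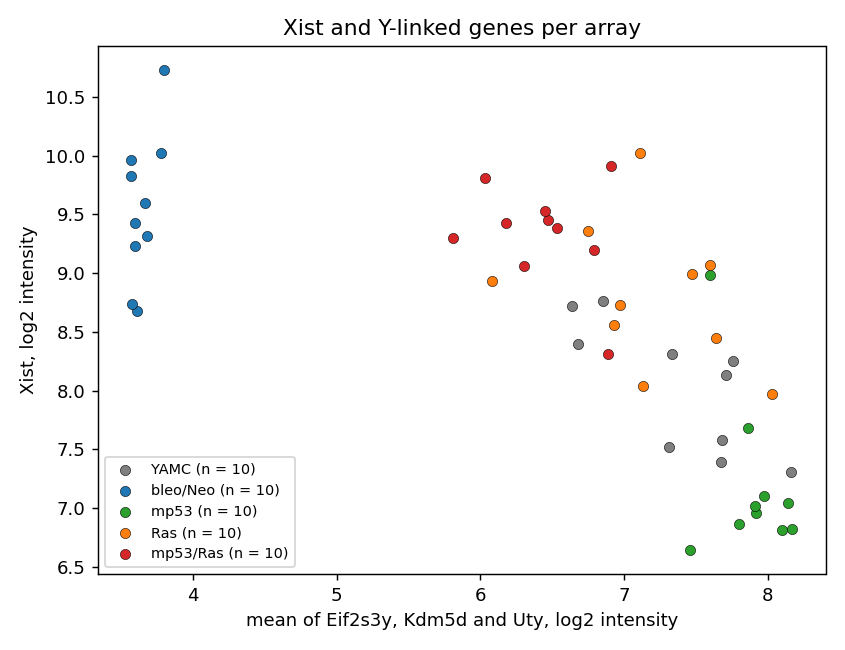
Xist level against the mean level of Eif2s3y, Kdm5d and Uty (both log2 intensity) for 50 arrays, coloured by group. All 10 bleo/Neo arrays have a low Y-linked mean (group mean 3.65), and the mp53 arrays have the lowest mean Xist level (7.19).

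Of 34 extracellular matrix genes, 22 fell in bleo/Neo, 2 rose and 10 did not pass (camera adjusted p = 3.98e-11; adjusted p = 0.0202 with an estimated correlation). Col8a1 (−4.54 ± 0.20) and the basement membrane gene Nid1 (−3.95 ± 0.22, with another bright probe set at −0.04) were among them, whereas the proteoglycan gene Dcn (1.44 ± 0.19) and the laminin gene Lama3 (0.21 ± 0.05) rose. Mesenchymal transition genes fell in 10 of 21 cases, rose in 3 and did not pass in 8 (adjusted p = 0.00231; adjusted p = 0.00715 with an estimated correlation), with the cadherin gene Cdh11 at −2.15 ± 0.22 and the secreted ligand gene Wnt5a at −1.53 ± 0.13. Interferon gamma and antigen presentation genes fell in 10 of 22 cases and rose in 4 (adjusted p = 0.00594), led by the class II gene H2-Aa (−3.31 ± 0.27). This call ended at adjusted p = 0.184 with an estimated correlation. Fibroblast and smooth muscle markers fell in 6 of 12 cases and rose in 1 (adjusted p = 0.00601; adjusted p = 0.184 with an estimated correlation), among them the smooth muscle actin gene Actg2 (−2.93 ± 0.32) and the calponin gene Cnn1 (−2.07 ± 0.21).

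Squamous and neural markers rose in 10 of 18 cases and fell in 3 (adjusted p = 0.0215; adjusted p = 0.263 with an estimated correlation), with the keratin gene Krt15 (1.96 ± 0.21) and Ivl, the cornified envelope protein involucrin (1.71 ± 0.36). Glycolysis and hypoxia genes fell in 13 of 26 cases and rose in 2 (adjusted p = 0.00601; adjusted p = 0.373 with an estimated correlation), for example Bnip3 (−1.50 ± 0.17). Of cholesterol synthesis genes 6 of 19 rose with none lower (adjusted p = 0.0304; adjusted p = 0.654 with an estimated correlation). Adjusted over the list alone, 22 matrix genes fell, 13 mesenchymal genes fell and 12 squamous and neural markers rose. All 10 bleo/Neo arrays that carry these lists are also the arrays low in Y-linked genes. Vector, selection and the expansion of this population cannot be separated, since 1 population represents the vectors.

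Mutant p53 alone was compared with bleo/Neo. Genes are ranked here among those whose arrays did not overlap, and the rise of Eif2s3y is given below. The other largest rises were in Plagl1, an imprinted zinc-finger transcription factor gene (6.05 ± 0.40), Rps4l (5.80 ± 0.13) and Myl9 (5.63 ± 0.28). Col1a2 (4.37 ± 0.14), Zic1 (4.11 ± 0.20), Actg2 (4.00 ± 0.32) and Bgn (3.93 ± 0.10) followed. Under the same rule the largest falls were in Kcnk1 (−5.22 ± 0.20) and Gpm6a (−4.33 ± 0.21). Next were Perp, a desmosome component and p53 target (−3.44 ± 0.30), and the keratin gene Krt19 (−3.10 ± 0.24). The rule left out Ddx4 (mean 9.01 in bleo/Neo, 5.66 in mp53), whose fall was larger than that of Krt19. Also lower were the microtubule-binding Hook1 (−3.07 ± 0.16), the mitochondrial creatine kinase gene Ckmt1 (−3.01 ± 0.20), Akr1c14 (−2.86 ± 0.17) and Stmn4 (−2.85 ± 0.11). Several of these differences were not found against YAMC. There mp53 cells were at 0.03 for Rps4l, 0.15 for Myl9, −0.24 for Col1a2 and −0.12 for Stmn4, none of which passed. Zic1 (−1.05), Bgn (−0.35), Gpm6a (0.82) and Akr1c14 (0.63) passed in the opposite direction. Plagl1 (1.47), Actg2 (1.07), Kcnk1 (−1.63), Perp (−2.03), Krt19 (−0.89), Hook1 (−0.72) and Ckmt1 (−0.60) passed the test in the same direction against YAMC, with smaller differences. Another bright Plagl1 probe set differed by 0.05 between mp53 and bleo/Neo.

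In mp53 cells 4562 genes changed against bleo/Neo, 2123 higher and 2439 lower, 414 of them at least 2-fold (215 higher, 199 lower). Against YAMC 2952 genes changed, and 1276 of the 4562 (28%) kept their direction and passed. Eif2s3y (5.23 ± 0.17), Kdm5d (3.76 ± 0.19) and Uty (3.74 ± 0.19) were higher than in bleo/Neo, and Xist was lower (−2.36 ± 0.25). Of the reference genes, Ccnd1 rose by 0.43 ± 0.10 (another bright probe set by 0.10) and Dusp6 fell by 0.66 ± 0.27, and neither passed against YAMC (0.14 and −0.44). Actb (0.15), Vim (0.15), Myc (0.05), Mdm2 (0.03), Nras (0.01) and Cdkn1a (−0.05) did not pass, although Mdm2 was lower than in YAMC (−0.22).

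Extracellular matrix genes rose in 18 of 34 cases against bleo/Neo, fell in 2 and did not pass in 14 (adjusted p = 1.07e-07), for example Col8a1 (3.77 ± 0.20) and Nid1 (2.74 ± 0.22, with another bright probe set at 0.02), while Dcn fell (−0.88 ± 0.19). This call ended at adjusted p = 0.0969 with an estimated correlation. Mesenchymal transition genes rose in 8 of 21 cases and fell in 1 (adjusted p = 0.00122; adjusted p = 0.00424 with an estimated correlation), with S100a4 (1.77 ± 0.25) and Cdh11 (1.76 ± 0.22). Matrix proteases and inhibitors rose in 10 of 22 cases and fell in 2 (adjusted p = 0.0247; adjusted p = 0.102 with an estimated correlation), chiefly the gelatinase gene Mmp2 (2.80 ± 0.10). Fibroblast and smooth muscle markers rose in 5 of 12 cases and fell in 1 (adjusted p = 0.0173; adjusted p = 0.212 with an estimated correlation). Glycolysis and hypoxia genes rose in 11 of 26 cases and fell in 3 (adjusted p = 0.0247; adjusted p = 0.553 with an estimated correlation), with the muscle enolase gene Eno3 at 1.74 ± 0.14 and the lactate exporter gene Slc16a3 at −1.28 ± 0.18. Cell cycle genes fell in 10 of 35 cases and none rose (adjusted p = 0.0173; adjusted p = 0.574 with an estimated correlation), the largest fall being −0.54 ± 0.12 in Cdc6, which loads the replicative helicase.

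Against YAMC none of these 6 lists was called in mp53 cells, and the adjusted p of the matrix list was 0.0619 in the opposite direction. Col8a1 (−0.76), Nid1 (−1.21) and Mmp2 (−0.39) passed lower and Dcn (0.56) higher in mp53 than in YAMC cells, the reverse of their differences from bleo/Neo, while Cdh11 (−0.39) and Slc16a3 (0.31) did not pass. The lists called against YAMC were type I interferon response (adjusted p = 7.39e-06), p53 target genes (0.0073) and interferon gamma and antigen presentation (0.0302), all lower in mp53 cells. Against bleo/Neo 8 of 34 p53 target genes fell and 1 rose, and the list was not called (adjusted p = 0.0793). When adjusted over the list alone, 19 matrix genes and 10 mesenchymal genes rose. The array labelled mp53 10 lies nearer Ras and mp53 8 nearer YAMC, and all 10 bleo/Neo arrays are low in Y-linked genes. Without the arrays labelled mp53 10 and Ras 10, 9 lists were called, 5 higher and 4 lower.

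Activated Ras alone was also compared with bleo/Neo. Ras cells had more Plac8, a small cysteine-rich protein gene (5.54 ± 0.23), and Hmga2, an architectural chromatin protein (4.76 ± 0.37). They also had more Prkar2b, a regulatory subunit of protein kinase A (4.34 ± 0.19), the T-box factor gene Tbx20 (4.13 ± 0.22) and Clca3a1, a chloride channel accessory protein (4.03 ± 0.24). They had less Kcnk1 (−5.58 ± 0.20), Plxdc2, a plexin-domain membrane protein (−4.40 ± 0.37), the proprotein convertase gene Pcsk5 (−4.32 ± 0.24), Col4a4, a basement membrane collagen chain (−3.60 ± 0.30), and the ephrin receptor gene Epha7 (−3.01 ± 0.20). Against YAMC, Hmga2 (3.13), Plxdc2 (−4.61), Pcsk5 (−2.92) and Col4a4 (−3.06) kept most of their difference. Plac8 (1.15), Prkar2b (1.64), Tbx20 (0.53), Clca3a1 (1.66), Kcnk1 (−1.99) and Epha7 (−0.54) kept a smaller part, which still passed. Rps4l (5.25 ± 0.13), Zic1 (4.82 ± 0.20), Eif2s3y (4.55 ± 0.17) and Gpm6a (−4.65 ± 0.21) also differed from bleo/Neo but were at −0.52, −0.34, −0.10 and 0.50 against YAMC. Bright probe sets ranged from 0.99 to 4.61 for Prkar2b and from −4.40 to −1.75 for Plxdc2. Akr1c14 (−3.47 ± 0.17) and Stmn4 (−3.03 ± 0.11) were at 0.02 and −0.30, and Stmn4 passed.

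In Ras cells 5301 genes changed against bleo/Neo, 2544 higher and 2757 lower, 522 of them at least 2-fold (269 higher, 253 lower). With YAMC as the control 5505 genes changed, and 2768 of the 5301 (52.2%) kept their direction and passed. Of the reference genes, Myc rose by 0.93 ± 0.17 (0.97 against YAMC) and Cdkn1a fell by 0.12 ± 0.03, which did not pass against YAMC (−0.06). Actb (0.03), Mdm2 (0.06), Nras (0.04) and Vim (0.14) did not pass, although Mdm2 was lower than in YAMC (−0.19).

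Glycolysis and hypoxia genes rose together in Ras cells, 19 of 26 with 3 lower (adjusted p = 2.98e-08), and also against YAMC (adjusted p = 0.000179). With an estimated correlation the adjusted p = 0.0549. Bnip3, a mitophagy receptor induced by hypoxia, rose by 2.65 ± 0.17, Eno3 by 1.94 ± 0.14, the aldolase gene Aldoc by 1.39 ± 0.19 and Pdk1, which restrains pyruvate entry into mitochondria, by 1.32 ± 0.16. Pfkfb3 (−0.66 ± 0.15), Ldhb (−0.64 ± 0.17) and Slc16a3 (−0.55 ± 0.18) fell; against YAMC Slc16a3 was 1.04 higher. MAPK feedback and ERK-induced genes rose in 16 of 24 cases and fell in 2 (adjusted p = 0.000235, 0.245 with an estimated correlation and 0.000135 against YAMC). They included the AP-1 gene Fosl1 (1.66 ± 0.24), the cyclin gene Ccnd1 (1.15 ± 0.10), the feedback inhibitor gene Spry4 (1.04 ± 0.10), Egr1 (1.02 ± 0.23) and the ERK phosphatase gene Dusp6 (0.94 ± 0.27). Chemokines and cytokines rose in 11 of 21 cases and fell in 4 (adjusted p = 0.0255; adjusted p = 0.432 with an estimated correlation), with Il6 at 2.36 ± 0.17 and Il18 at −1.21 ± 0.10. Against YAMC the list was not called (adjusted p = 0.163). Matrix proteases and inhibitors rose in 11 of 22 cases and fell in 3 (adjusted p = 0.0129; adjusted p = 0.0549 with an estimated correlation). The collagenase gene Mmp13 (3.12 ± 0.37) and the stromelysin gene Mmp10 (2.41 ± 0.15) were higher and the aggrecanase gene Adamts5 lower (−1.72 ± 0.20). Mesenchymal transition genes rose in 10 of 21 cases and fell in 4 (adjusted p = 0.0166; adjusted p = 0.0549 with an estimated correlation), led by S100a4 (3.25 ± 0.25). Neither the protease list (adjusted p = 0.635) nor the mesenchymal list (0.691) was called against YAMC. Lists called against YAMC alone, all lower in Ras cells, were extracellular matrix (adjusted p = 5.48e-08), fibroblast and smooth muscle markers (0.000396), TGF-beta and BMP pathway (0.00459) and Wnt pathway (0.01).

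Ribosomal proteins and translation factors rose in 14 of 30 cases and fell in 1, by small amounts such as 0.60 ± 0.15 for Rps25 (adjusted p = 0.0129; adjusted p = 0.366 with an estimated correlation). Cholesterol synthesis genes rose in 9 of 19 cases and fell in 1 (adjusted p = 0.0302; adjusted p = 0.715 with an estimated correlation), for example Sqle, squalene epoxidase (0.67 ± 0.18). Unfolded protein and amino acid response genes fell in 15 of 30 cases and rose in 1 (adjusted p = 0.0273; adjusted p = 0.715 with an estimated correlation), among them Herpud1 (−0.76 ± 0.17) and the amino acid transporter gene Slc7a5 (−0.72 ± 0.12). Of 34 p53 target genes, 13 fell and 1 rose (adjusted p = 0.0284; adjusted p = 0.331 with an estimated correlation), with Pmaip1, a proapoptotic BH3-only protein, at −2.43 ± 0.21. These 4 lists were also called against YAMC, in the same directions. Adjusted over the list alone, 16 ribosomal and translation genes, 12 chemokines and 10 cholesterol genes rose. The array labelled Ras 10 lies nearer mp53, with Hmga2 at 8.58 against 12.33 to 12.80 in the other Ras arrays, and all 10 bleo/Neo arrays are low in Y-linked genes.

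The joint effect of both oncogenes was measured as mp53/Ras against bleo/Neo. The 10 mp53/Ras arrays all lay above the 10 bleo/Neo arrays for Plac8 (6.21 ± 0.23, adjusted p = 3.81e-28), Hmga2 (5.09 ± 0.37), Cadm1, an adhesion molecule of the immunoglobulin family (4.79 ± 0.32), and Prkar2b (4.65 ± 0.19). The same was seen for Clca3a1 (4.54 ± 0.24), the troponin gene Tnnt2 (4.21 ± 0.24) and Fgf7, the keratinocyte growth factor (4.13 ± 0.27). All lay below for Kcnk1 (−5.79 ± 0.20, adjusted p = 2.26e-29), Plxdc2 (−4.89 ± 0.37), Pmaip1 (−4.83 ± 0.21), the stathmin gene Stmn4 (−4.28 ± 0.11) and Arhgap24 (−4.03 ± 0.13). The same held for Npr3, the natriuretic peptide clearance receptor (−3.92 ± 0.23), the melanosome transport gene Mreg (−3.90 ± 0.18), Perp (−3.86 ± 0.30) and Ckmt1 (−3.64 ± 0.20). Measured against YAMC, Hmga2 (3.46), Cadm1 (3.85), Tnnt2 (3.41), Fgf7 (3.62), Plxdc2 (−5.10), Pmaip1 (−4.41), Arhgap24 (−3.80), Npr3 (−3.37) and Mreg (−3.42) differed in the same direction by more than 3. Plac8 (1.82), Prkar2b (1.95), Clca3a1 (2.17), Kcnk1 (−2.20), Stmn4 (−1.54), Perp (−2.45) and Ckmt1 (−1.24) differed by less, also in the same direction. The direction turned for Rps4l (5.03 ± 0.13 against bleo/Neo, −0.74 against YAMC), Zic1 (4.68 ± 0.20 and −0.48), Eif2s3y (4.21 ± 0.17 and −0.45) and Gpm6a (−4.17 ± 0.21 and 0.99).

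In all, 7032 genes changed, 3438 higher and 3594 lower, and 894 changed at least 2-fold, of which 362 were higher and 532 lower. Against YAMC 7444 changed, and 4830 of the 7032 (68.7%) kept their direction and passed. The gene means in bleo/Neo and mp53/Ras cells were 5.55 and 11.76 for Plac8, 10.80 and 5.01 for Kcnk1, and 11.20 and 6.37 for Pmaip1. Bright probe sets of the same gene differed in size, from 1.23 to 4.79 for Cadm1, from 1.35 to 4.93 for Prkar2b, from −3.92 to −0.90 for Npr3, from −4.89 to −1.80 for Plxdc2 and from −4.03 to −0.16 for Arhgap24.

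**Figure D3:**
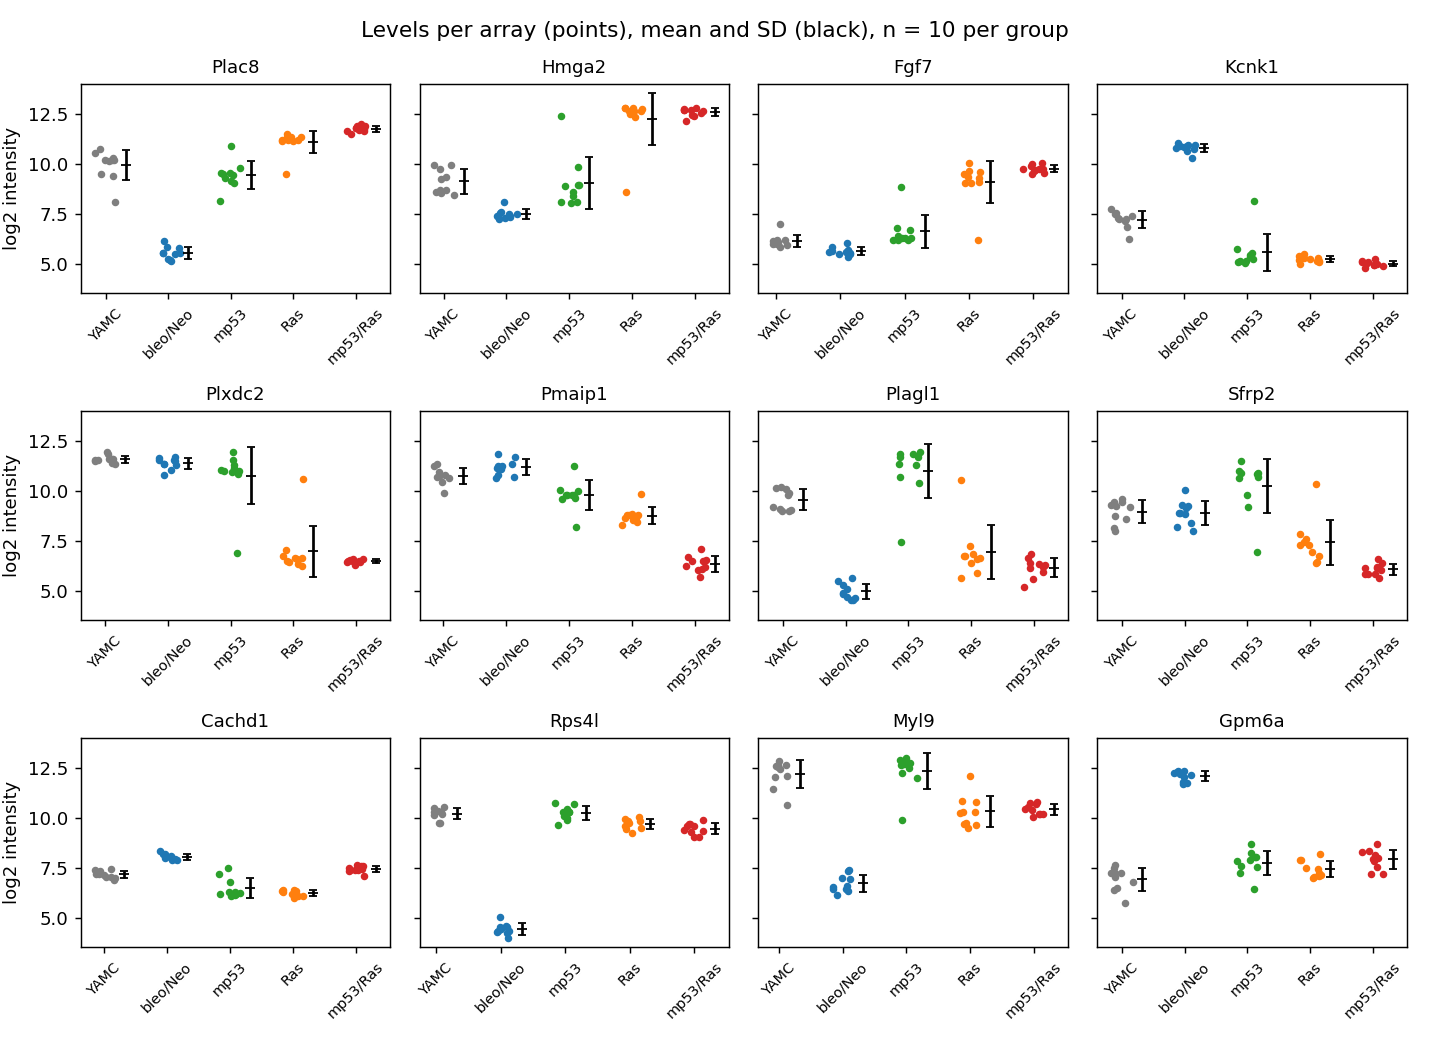
Log2 intensity of 12 genes (1 panel each) on every array, by group, with the group mean and standard deviation in black (n = 10 per group). Plac8, Hmga2 and Fgf7 are highest in mp53/Ras cells (means 11.76, 12.58 and 9.76), and Rps4l, Myl9 and Gpm6a set bleo/Neo apart from the other 4 groups.

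p53 target genes fell as a group in mp53/Ras cells, 25 of 34 with 3 higher and 6 not passing (adjusted p = 7.18e-07; adjusted p = 0.00753 with an estimated correlation). Beside Pmaip1 and Perp these included Rprm, a mediator of G2 arrest (−1.77 ± 0.19), the death receptor gene Fas (−1.71 ± 0.12), Mdm2 (−0.44 ± 0.07, with another bright probe set at −0.02) and the cell cycle inhibitor gene Cdkn1a (−0.39 ± 0.03). Cdkn1a lay between 13.39 and 13.78 in the group means, near the highest value of the table (14.26), where saturation can shrink a difference. The kinase genes Plk3 (0.43 ± 0.10) and Plk2 (0.28 ± 0.09) and the growth factor gene Tgfa (0.26 ± 0.06) rose. The list was also lower against YAMC (adjusted p = 1.94e-07). Glycolysis and hypoxia genes rose in 21 of 26 cases and fell in 2 (adjusted p = 7.09e-08, and 8.34e-05 against YAMC; adjusted p = 0.0653 with an estimated correlation). Eno3 rose by 3.27 ± 0.14, Bnip3 by 2.97 ± 0.17, Pdk1 by 1.51 ± 0.16 and the phosphofructokinase gene Pfkl by 1.47 ± 0.14, while Ldhb (−2.08 ± 0.17) and Eno2 (−1.28 ± 0.20) fell. MAPK feedback and ERK-induced genes rose in 18 of 24 cases and fell in 3 (adjusted p = 0.00222, 0.275 with an estimated correlation and 0.00165 against YAMC). Fosl1 (1.51 ± 0.24), Myc (1.40 ± 0.17), Ccnd1 (1.12 ± 0.10), Dusp5 (1.05 ± 0.11) and Dusp6 (1.05 ± 0.27) rose, and the cytokine gene Il11 (−0.80 ± 0.09), Fos (−0.75 ± 0.21) and Spry1 (−0.49 ± 0.14) fell.

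Chemokines and cytokines rose in 10 of 21 cases and fell in 2 (adjusted p = 0.00825, and 0.0491 against YAMC; adjusted p = 0.275 with an estimated correlation). Cxcl12 (3.25 ± 0.29, with bright probe sets from −0.13 to 3.73), Il6 (2.63 ± 0.17) and Ccl9 (2.55 ± 0.14) were higher and Il18 (−1.36 ± 0.10) lower. Mesenchymal transition genes rose in 13 of 21 cases and fell in 4 (adjusted p = 0.0104; adjusted p = 0.033 with an estimated correlation), with S100a4 (3.72 ± 0.25) and the transcription factor gene Twist2 (1.66 ± 0.16) higher and Tgfb2 (−1.30 ± 0.18) lower, but the list was not called against YAMC (adjusted p = 0.863). Ribosomal proteins and translation factors rose in 19 of 30 cases and fell in 1, by a median of 0.13 (adjusted p = 0.00741; adjusted p = 0.275 with an estimated correlation). Cholesterol synthesis genes rose in 13 of 19 cases, for example Sc5d (0.90 ± 0.13), and Dhcr7 fell by 0.45 ± 0.09, but not against YAMC, where it was at 0.17 (adjusted p of the list 0.0407, and 0.735 with an estimated correlation). Adjusted over the list alone, 11 chemokines and cytokines rose and 4 MAPK and ERK genes fell, and the counts of the other 5 lists were those given. Among reference genes, Actb rose by 0.20 ± 0.07 (bright probe sets from −0.10 to 0.20), Vim rose by 0.17 ± 0.07, and Nras, at 0.18 ± 0.12, did not pass (adjusted p = 0.212). Against YAMC the 3 genes were at 0.04, 0.01 and 0.04, and none passed.

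Lists not called in mp53/Ras against bleo/Neo held genes moving both ways. Of matrix proteases and inhibitors 12 of 22 rose and 5 fell (adjusted p = 0.0893), of Hox genes 11 of 24 rose and 6 fell (0.2), and of cell cycle genes 8 of 35 rose and 15 fell (0.238). Of TGF-beta and BMP pathway genes 8 of 29 rose and 17 fell (0.238), and of epithelial junction and keratin genes 6 of 25 rose and 11 fell (0.238). Unfolded protein and amino acid response genes rose in 4 of 30 cases and fell in 13 (0.375), Wnt pathway genes rose in 12 of 34 and fell in 15 (0.431), and type I interferon genes rose in 4 of 25 and fell in 6 (0.431). BCL2 family and death receptor genes rose in 9 of 29 cases and fell in 12 (0.547), and EGF family genes rose in 2 of 10 and fell in 3 (0.547). Squamous and neural markers rose in 4 of 18 and fell in 7 (0.633), and endothelial and immune markers rose in 2 of 11 and fell in 3 (0.748). Notch pathway genes rose in 8 of 22 cases and fell in 7 (0.841), colon epithelial differentiation markers rose in 2 of 13 and fell in 2 (0.841), and fibroblast and smooth muscle markers rose in 5 of 12 and fell in 5 (0.887). Extracellular matrix genes rose in 7 of 34 cases and fell in 11, with a median of −0.11, a mean of 0.26 and a test directed upwards (0.748), and against YAMC the list was lower (adjusted p = 2.61e-06). Interferon gamma genes rose in 8 of 22 cases and fell in 8, with a positive median of 0.06 and a test directed downwards (0.841), and against YAMC they were lower (0.00618). Also called against YAMC were the TGF-beta (0.00681), type I interferon (0.0289), unfolded protein (0.0289) and Wnt (0.0368) lists, all lower, and the Hox list (0.0377), higher. The median was positive and the mean negative for the EGF family, epithelial junction and keratin, BCL2 family, Notch and endothelial and immune lists, all with a test directed downwards, and the fibroblast list had a negative median and mean and a test directed upwards.

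**Figure D4:**
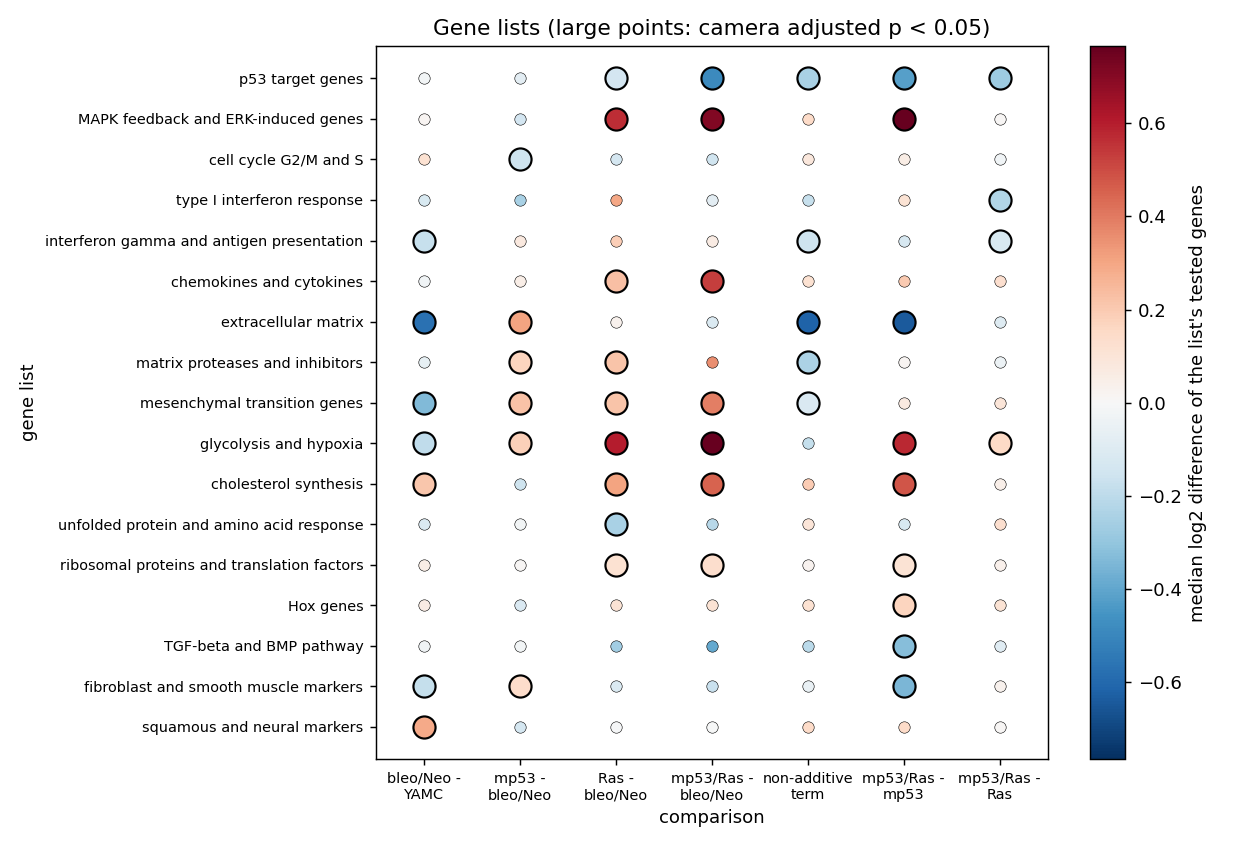
Median log2 difference (colour) of the tested genes of each gene list (vertical axis) in 7 comparisons (horizontal axis), for the described lists called in at least 1 of them; large points mark camera adjusted p values under 0.05. p53 target genes are blue in every comparison that contains mp53/Ras, and extracellular matrix genes are blue for bleo/Neo against YAMC (median −0.57) and for the non-additive term (−0.62).

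What Ras added to mutant p53 was measured as mp53/Ras against mp53, a comparison without bleo/Neo. Among genes whose arrays did not overlap, the largest rises were in Ank, a pyrophosphate transporter (3.70 ± 0.27), Fgf7 (3.15 ± 0.27) and Tnnt2 (3.13 ± 0.24). The ankyrin repeat gene Ankrd1 (3.09 ± 0.18) and the urea transporter gene Slc14a1 (3.07 ± 0.20) followed. Ddx4 (means 5.66 in mp53, 9.40 in mp53/Ras), Cadm1 (6.35, 9.99) and Hmga2 (9.03, 12.58) differed as widely, but their arrays overlapped. Under the same rule the largest falls were in Plagl1 (−4.86 ± 0.40, with another bright probe set at 0.09) and Plxdc2 (−4.28 ± 0.37, bright probe sets up to −0.91). Next were Sfrp2, a secreted Wnt antagonist (−4.18 ± 0.37), Id4, an inhibitor of basic helix-loop-helix factors (−3.48 ± 0.28, bright probe sets up to −1.09), and Pmaip1 (−3.43 ± 0.21). In total 6071 genes changed, 2999 higher and 3072 lower, 477 of them at least 2-fold (210 higher, 267 lower).

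Of 34 p53 target genes, 21 fell and 3 rose (adjusted p = 8.4e-07; adjusted p = 0.00801 with an estimated correlation), although both groups carried mutant p53. With the estimated correlation the p53 list alone held, and the other 8 called lists did not. Glycolysis and hypoxia genes rose in 19 of 26 cases and fell in 3 (adjusted p = 4.59e-07; adjusted p = 0.143 with an estimated correlation), with Slc16a3 at 1.98 ± 0.18. MAPK feedback and ERK-induced genes rose in 15 of 24 cases and fell in 1 (adjusted p = 1.64e-05; adjusted p = 0.149 with an estimated correlation), with Dusp6 at 1.71 ± 0.27 and Dusp4 at 1.51 ± 0.22. Extracellular matrix genes fell in 24 of 34 cases and rose in 3 (adjusted p = 1.64e-05; adjusted p = 0.149 with an estimated correlation), for example Nid2 (−1.69 ± 0.19), tenascin Tnc (−1.53 ± 0.24) and periostin Postn (−1.45 ± 0.14). Cholesterol synthesis genes rose in 15 of 19 cases (adjusted p = 4.21e-05; adjusted p = 0.264 with an estimated correlation) and Hox genes in 10 of 24 with 1 lower (adjusted p = 0.00126; adjusted p = 0.149 with an estimated correlation), including Hoxd10 (1.55 ± 0.28) and Hoxc10 (1.33 ± 0.16). Ribosomal and translation genes rose in 13 of 30 cases (adjusted p = 0.0016; adjusted p = 0.228 with an estimated correlation). TGF-beta and BMP pathway genes fell in 16 of 29 cases and rose in 5 (adjusted p = 0.0207; adjusted p = 0.293 with an estimated correlation), with Id2 at −1.64 ± 0.25. Fibroblast and smooth muscle markers fell in 7 of 12 cases and rose in 3 (adjusted p = 0.0284; adjusted p = 0.264 with an estimated correlation), with the microfibril gene Mfap5 at −1.99 ± 0.23. Adjusted over the list alone, 22 p53 targets fell, 17 cholesterol genes rose and 8 fibroblast markers fell.

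What mutant p53 added to Ras was smaller. In mp53/Ras against Ras 2779 genes changed, 1175 higher and 1604 lower, and 120 changed at least 2-fold, 23 higher and 97 lower. Fgfr1, a fibroblast growth factor receptor, rose by 2.27 ± 0.18, Pla2g7, which degrades platelet-activating factor, by 1.50 ± 0.18, the F-box gene Fbxo17 by 1.50 ± 0.11, the semaphorin gene Sema7a by 1.43 ± 0.12 and Eno3 by 1.33 ± 0.14. Among genes whose arrays did not overlap, the largest falls were in Pmaip1 (−2.40 ± 0.21), the apolipoprotein L gene Apol8 (−2.25 ± 0.19) and Mreg (−2.24 ± 0.18). Next were Arhgap24 (−2.22 ± 0.13) and the polarity scaffold gene Mpp7 (−2.14 ± 0.15), with other bright probe sets at −0.17 for Arhgap24 and up to −0.74 for Mpp7. Of 34 p53 target genes, 20 fell and 1 rose (adjusted p = 1.52e-11; adjusted p = 0.000118 with an estimated correlation), with Perp at −2.05 ± 0.30, Rprm at −1.49 ± 0.19 and the kinase gene Dgka at −1.20 ± 0.14. Type I interferon response genes fell in 8 of 25 cases and none rose (adjusted p = 0.00116; adjusted p = 0.711 with an estimated correlation), and interferon gamma genes fell in 7 of 22 (adjusted p = 0.0168; adjusted p = 0.523 with an estimated correlation), with −0.75 ± 0.18 for Ifit3 and −0.72 ± 0.09 for the peptide transporter gene Tap1. Glycolysis and hypoxia genes rose in 4 of 26 cases and fell in 2 (adjusted p = 0.0487; adjusted p = 0.711 with an estimated correlation). When adjusted over the list alone, 21 p53 targets fell and 2 rose. The arrays labelled Ras 10 and mp53 10, each nearer the other's group, are part of the Ras and mp53 groups in both comparisons.

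The series asks which genes respond to both oncogenes together differently from the sum of their separate effects. This was tested as mp53/Ras minus mp53 minus Ras plus bleo/Neo, on the log2 scale. With bleo/Neo as the baseline, 3073 genes were non-additive, 1524 positive and 1549 negative, and 402 by at least 2-fold (163 and 239). The largest positive terms were in Kcnk1 (5.01 ± 0.29), Gpm6a (4.82 ± 0.29), the cell adhesion gene Esam (3.58 ± 0.13), Akr1c14 (3.07 ± 0.24) and Cachd1 (2.76 ± 0.16), then Akr1e1 (2.67 ± 0.21), Krt19 (2.60 ± 0.34) and Hook1 (2.56 ± 0.22). The largest negative terms were in Plagl1 (−6.82 ± 0.56), Rps4l (−6.03 ± 0.18), Eif2s3y (−5.57 ± 0.24), Myl9 (−5.53 ± 0.40), Kdm5d (−4.82 ± 0.27), Uty (−4.54 ± 0.28), the class I gene H2-Q5 (−4.47 ± 0.20) and Zic1 (−4.25 ± 0.28). Kcnk1, Akr1c14 and Hook1 were already at 5.58, 5.16 and 4.85 in mp53 and at 5.22, 4.55 and 4.96 in Ras cells, under the median of the table (6.44). Additive effects would put them at 0, 1.69 and 1.89 in mp53/Ras cells, below the lowest value of the table (3.04), so their positive terms can follow from background alone. For Gpm6a the additive level is 3.12, also near it. The negative terms of Eif2s3y, Kdm5d, Uty and Zic1 include a bleo/Neo level near background. For Rps4l and Myl9 the additive levels are 15.51 and 15.97, above the highest value of the table (14.26). Part of their negative terms can follow from that upper limit. Many of these terms rest on bleo/Neo, because any difference between bleo/Neo and YAMC enters the term in full. With YAMC as the baseline Gpm6a was −0.34, Akr1c14 −0.41, Rps4l −0.26, Myl9 −0.06 and H2-Q5 −0.52, and none of these passed. Another bright H2-Q5 probe set was at 0.51 with bleo/Neo, the opposite sign. Neither did Krt19 (0.40) and Hook1 (0.21), and Zic1 turned to 0.91.

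With YAMC as the baseline 1602 genes were non-additive, 145 by at least 2-fold. The number non-additive with the same sign on both baselines, a count chosen after seeing the data, was 769, of which 351 were positive and 418 negative, against 191 for independent lists. The baselines share the other 3 groups, which by itself raises the overlap. On both baselines 54 genes were at least 2-fold non-additive, 27 of each sign.

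Genes with large terms on both baselines included Misp3 (2.38 ± 0.24 with bleo/Neo, 2.45 with YAMC), Cachd1 (2.76 and 1.88), Fgfr1 (1.67 ± 0.25 and 3.46), and Hoxd10 (2.33 ± 0.39 and 1.86). Others were the basement membrane collagens Col4a4 (2.31 ± 0.43 and 1.78) and Col4a3 (1.96 ± 0.23 and 1.64), and Slc14a1 (1.69 ± 0.28 and 1.81). Additive effects would put Misp3 at 3.40 and 3.33 on the 2 baselines, Col4a4 at 2.95 and 3.49 and Col4a3 at 2.89 and 3.21. These levels lie near or below the lowest value of the table, so the terms of the 2 collagens can follow from background too. Background can also enlarge the Misp3 term, but mean Misp3 was higher in mp53/Ras cells (5.78) than in mp53 (5.29) and Ras cells (4.95). Negative on both were Sfrp2 (−2.72 ± 0.53 and −2.64), Plagl1 (−6.82 and −2.24, with another bright probe set at −0.04 on the bleo/Neo baseline) and the glutathione transferase gene Mgst2 (−2.54 ± 0.22 and −1.76). So were Igf2, an imprinted growth factor (−1.61 ± 0.43 and −2.55), Arhgap24 (−1.43 ± 0.19 and −1.67), Id4 (−1.37 ± 0.40 and −1.45) and the myosin light chain kinase gene Mylk (−2.33 ± 0.29 and −1.31). With bleo/Neo, bright probe sets reached −0.35 for Arhgap24, −0.28 for Id4 and −0.09 for Mylk. Sfrp2 levels were 8.98 in YAMC, 8.90 in bleo/Neo, 10.26 in mp53, 7.44 in Ras and 6.07 in mp53/Ras cells. Fgfr1 levels were 7.94, 6.14, 6.75, 5.96 and 8.23 in the same order.

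**Figure D5:**
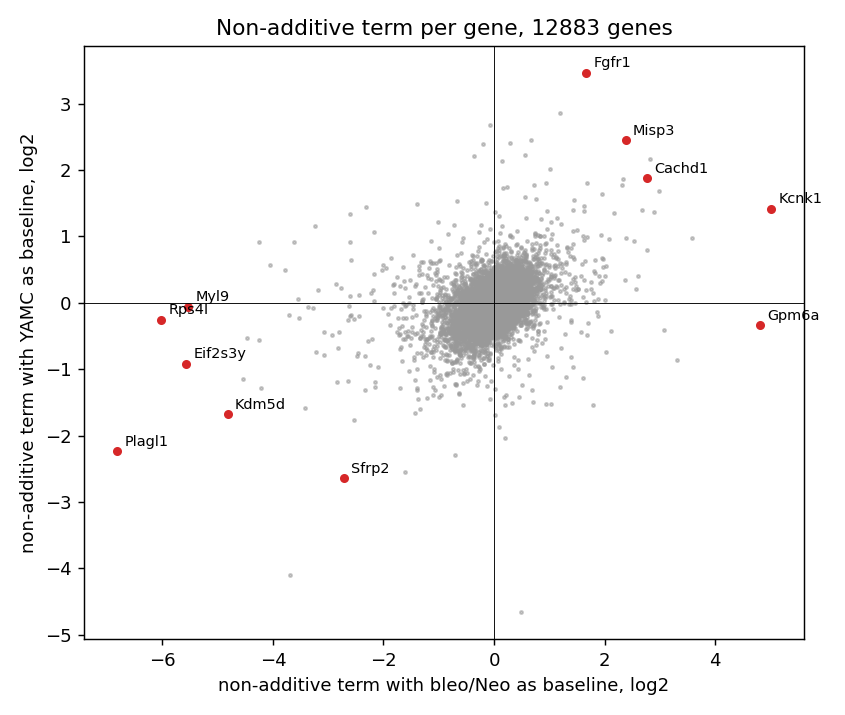
Non-additive term (log2) of 12883 genes with bleo/Neo as the baseline (horizontal axis) and with YAMC as the baseline (vertical axis), with named genes in red. Misp3, Cachd1, Fgfr1, Sfrp2 and Plagl1 lie away from 0 on both axes, whereas Rps4l, Myl9 and Gpm6a lie away from 0 on the horizontal axis.

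There were 6 lists with shifted non-additive terms when bleo/Neo was the baseline, of which 5 are described. With the replicate number as a block, the number of lists called was 5. Extracellular matrix genes were negative in 19 of 34 cases and positive in 2 (adjusted p = 7.8e-09, and 0.0378 with an estimated correlation). Col1a2 (−4.05 ± 0.20) and Bgn (−3.79 ± 0.14) led them. Additive effects would put Col1a2 at 16.45 and Bgn at 16.54, above the highest value of the table (14.26). Part of these 2 terms can follow from that limit. The additive level of Mmp2, named next, is 14.43, slightly above it. Matrix proteases and inhibitors were negative in 7 of 22 cases (adjusted p = 0.00662; adjusted p = 0.0378 with an estimated correlation), with Mmp2 at −3.27 ± 0.14 and Mmp10 at −1.39 ± 0.22. Interferon gamma genes were negative in 9 of 22 cases and positive in 2 (adjusted p = 0.00662; adjusted p = 0.142 with an estimated correlation), with H2-Aa at −3.53 ± 0.38 (bright probe sets up to −1.31). Mesenchymal transition genes were negative in 6 of 21 cases and positive in 1 (adjusted p = 0.0468; adjusted p = 0.0661 with an estimated correlation). p53 target genes were negative in 12 of 34 cases and positive in 1 (adjusted p = 0.00662, and 0.113 with an estimated correlation), with Pmaip1 at −1.0 ± 0.30, Rprm at −0.85 ± 0.27 and Tap1 at −0.63 ± 0.12. The positive member was Perp, at 8.55 in mp53/Ras cells, above its additive level of 7.16 with bleo/Neo. With YAMC its additive level was 8.57, about the level observed. Positive terms were called on the YAMC baseline for glycolysis and hypoxia genes (adjusted p = 0.0393) and for unfolded protein and amino acid response genes (adjusted p = 0.00801), neither of which was called with bleo/Neo. On the YAMC baseline the p53 list was the only of these 5 that was called (adjusted p = 0.00208), while Col1a2 was at 0.57, Bgn at 0.49, Mmp2 at −0.08 and H2-Aa at −0.23. Adjusted over the list alone, 21 matrix genes and 13 p53 targets were negative. The bleo/Neo arrays on which the other 4 lists rest are the 10 arrays low in Y-linked genes.

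On the linear scale, 1661 genes met the description of more than the summed level or less than either single level in mp53/Ras cells, 27 of them higher and 1634 lower (761 with a limit of 0.8), and 397 of these were also non-additive with the same sign. Its higher arm must exceed a sum of 2 full levels, so the definition itself makes it the rarer. The description has no test of its own and uses bleo/Neo through the call of changed genes; with YAMC in its place the number was 1782. mp53 and Ras differences from bleo/Neo correlated across genes (Pearson r = 0.674, covariance 0.14, same sign in 71.3%), although genes are not independent replicates. Unchanged groups with a shared control were simulated from the deviations of all 50 arrays, from every group, from their group means. These gave a mean r of 0.477 (standard deviation 0.203), a covariance of 0.00621 and the same sign in 66.3%. By r alone the observed value therefore does not stand apart from unchanged groups. The observed covariance was larger by 0.134. Arrays that lie nearer another group were among those drawn from, which can raise the simulated r. With the bleo/Neo arrays split between the comparisons the mean r was 0.627 and the covariance 0.134. Rises shared by both comparisons numbered 1222 and shared falls numbered 1436, counts that the common bleo/Neo arrays raise by themselves. With both groups compared with YAMC the correlation was 0.493, and with mp53 compared with bleo/Neo and Ras with YAMC it was −0.05. The last value cannot show what the shared control adds. The 2 controls themselves differ (root mean square 0.429), and that difference enters it.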

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

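The tests of arrays that resemble another group, the tests of Y-linked genes and Xist, and the count of genes on both baselines were chosen only after the result had been seen. Levels of 16 genes and the distance of each array from its group mean were examined in 85 groups of 10 arrays. In 26 of them 1 array stood far from the other 9, whereas chance does this in about 1 in 20 groups (5%). The arrays labelled mp53 10, Ras 10, YAMC 2 and mp53 8 account for 20 of the 26.

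The arrays labelled mp53 10 and Ras 10 each resembled the other's group: of 514 genes that differ 2-fold between mp53 and Ras, 84.2% and 88.1% were nearer the other group's mean, against at most 6.19% in 17 undoubted arrays. Poor array quality is argued against, because Ras 10 lay 0.304 (root mean square) and mp53 10 lay 0.288 from the other group's mean, within the 0.389 that undoubted arrays lay from their own. RNA mixed with at least an equal part of the labelled group's own is argued against by median own-group fractions of 0.15 in mp53 10 and 0.0928 in Ras 10. An exchange of the labels of the 2 arrays is consistent with all these values and remains a hypothesis, and no biological explanation was tested.

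Levels set mp53 10 and Ras 10 apart (ranges of the other 9 arrays in brackets). Hmga2 was 12.42 in mp53 10 (8.03 to 9.84) and 8.58 in Ras 10 (12.33 to 12.80), and Plxdc2 was 6.89 (10.87 to 11.98) and 10.60 (6.24 to 7.04). Plagl1 was 7.45 (10.42 to 11.94) and 10.54 (5.66 to 7.24), Myl9 was 9.91 (12.02 to 13) and 12.12 (9.53 to 10.86), and Fgf7 was 8.87 (6.18 to 6.80) and 6.21 (9.03 to 10.03). Sfrp2 was 6.96 (9.22 to 11.53) and 10.35 (6.39 to 7.86). In mp53 10 Xist was 8.98 (6.64 to 7.68). In Ras 10 Plac8 was 9.52 (11.13 to 11.48), Pmaip1 was 9.84 (8.30 to 8.83), and the distance from the group mean was 0.489 (0.17 to 0.282).

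The arrays labelled YAMC 2 and mp53 8 also resembled each other's group: of 205 genes that differ 2-fold, 69.8% and 88.8% were nearer the other group's mean, against at most 16.6% in 17 undoubted arrays. YAMC 2 stood apart in Plac8 (8.11, the others 9.39 to 10.76), Fgf7 (7.0, the others 5.84 to 6.21) and the distance from its group mean (0.517, the others 0.196 to 0.348), and mp53 8 in Kcnk1 (8.15, the others 5.05 to 5.74). RNA mixed with at least an equal part of the labelled group's own is argued against by median own-group fractions of 0.154 in mp53 8 and 0.0643 in YAMC 2. An exchange of the 2 labels is consistent with these shares, but YAMC 2 lay 0.511 from the mp53 mean, beyond the 0.389 of undoubted arrays, and mp53 8 lay 0.379 from the YAMC mean. Poor quality of YAMC 2 and an exchange therefore cannot be told apart, and no biological explanation was tested.

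All 10 bleo/Neo arrays lay below the 40 other arrays for the 3 Y-linked genes, by at least 2.98 on average per gene. A technical loss of signal across the arrays is argued against, since 7 of 7125 equally bright genes (0.0982%) lay as far below. Loss of the Y chromosome from male cells would leave Xist no higher than in YAMC, and it was higher by 1.52, but mp53/Ras cells, which keep Y-linked transcripts, did not differ from bleo/Neo in Xist past the test (−0.215, adjusted p = 0.486). A YAMC line that mixes cells with and without a Y chromosome, of which bleo/Neo came from cells without, would make Xist and the Y-linked mean run against each other, and over the 10 YAMC arrays r was −0.758 (permutation p = 0.015, adjusted over 5 relations 0.075; −0.665 without the 2 farthest arrays), with Spearman's coefficient at −0.685 (p = 0.035, adjusted 0.18). Over the 5 groups, mean Xist rose in the order in which the Y-linked mean fell, an order that a mixture would give. Loss of the Y chromosome alone does not account for that order. It is nevertheless not excluded, because the order rests on 5 group means seen before the question was put. Within groups no relation passed after adjustment, and the arrays are few. A different origin of the bleo/Neo cells stays open and untested.

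Apart from these, Hmga2 in bleo/Neo 7 was 8.11 (the other 9 arrays 7.26 to 7.57) and Kcnk1 in bleo/Neo 3 was 10.28 (10.66 to 11.03). Kdm5d in bleo/Neo 1 was 4.35 (3.43 to 3.67). In mp53/Ras cells Plxdc2 was 6.28 in array 3 (6.45 to 6.61), Cachd1 was 7.09 in array 4 (7.38 to 7.66) and Xist was 8.31 in array 8 (9.06 to 9.91).

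With bleo/Neo as the baseline, the effect of Ras differed between cells with and without mutant p53, by the non-additive term, for 3073 genes, 402 of them by at least 2-fold; 769 of the 3073 had the same sign and passed with YAMC. Terms were 5.01 for Kcnk1, 4.82 for Gpm6a, 3.58 for Esam, 3.07 for Akr1c14, 2.76 for Cachd1, 2.67 for Akr1e1, 2.60 for Krt19 and 2.56 for Hook1. They were −6.82 for Plagl1, −6.03 for Rps4l, −5.57 for Eif2s3y, −5.53 for Myl9, −4.82 for Kdm5d, −4.54 for Uty, −4.47 for H2-Q5 (another bright probe set 0.51) and −4.25 for Zic1. With YAMC as the baseline Gpm6a, Akr1c14, Krt19, Hook1, Rps4l, Myl9 and H2-Q5 did not pass, and Zic1 turned to 0.91. Among probe sets without a single gene symbol, which no comparison uses, 1264 of 2869 changed in mp53/Ras against bleo/Neo, 107 of them at least 2-fold (60 higher, 47 lower).

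Chance was examined with 100 splits of the same arrays for each result, the real one included. A chance division of the arrays is unlikely for the gene counts that the real split alone (1 of 100) reached. These were mp53/Ras against bleo/Neo 7032 (highest other 5743), at 2-fold 894 (602), mp53 4562 (1200) and Ras 5301 (377). Others were bleo/Neo against YAMC 4813 (1756), mp53/Ras against mp53 6071 (2782) and against Ras 2779 (477). The shares were not adjusted for being several, and 1 of 100 is the smallest possible. Each population exists once, so such splits cannot exclude differences between independent derivations. The real split alone also reached the non-additive genes, 3073 (41) and 402 at 2-fold (18), and the linear description, 1661 (81). Those splits shuffle all the compared groups together, which removes the separate mp53 and Ras effects too. They therefore cannot tell non-additive from additive effects. Of the list counts, the 9 lists for Ras were reached by 3 of 100 splits (highest other 10). The list counts were not adjusted for being several, so chance is less likely for Ras but not excluded. For Ras 0 lists are called by camera with an estimated correlation (4 at an unadjusted p under 0.05) and 15 by fry. Chance cannot be excluded for mp53/Ras, 7 lists (highest other 11, 17 splits), or for mp53, 6 lists (9, 22 splits). Nor can it be for the non-additive term, 6 lists (14, 29 splits). The other splits called a median of 3 lists in Ras, mp53 and mp53/Ras and 4 for the non-additive term. The 769 genes non-additive with the same sign on both baselines were reached by 2 of 100 splits, the real one and another with 1498. This count was chosen after seeing the data, and its splits shuffle all 5 groups, which removes the additive effects too. Chance can therefore not be excluded for it, and what the other split has in common was not examined.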

How the results depend on the processing

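The settings without 2 or 4 arrays, the comparison of both oncogenes with YAMC and the count on both baselines were chosen after seeing the data. Quantile normalisation and centring on medians test nothing here, because the deposited values are already quantile-normalised. Arrays have no read depth; genes near the lowest value of the table (3.04) are not separable from background without detection calls, which limits what small changes of dim genes can show. Replicate numbers share part of the variation: mean r was 0.0461 to 0.313 for same-numbered and −0.031 to −0.00531 for other arrays, and 23 of 50 arrays correlated best with their own number. They were not used as pairs, because the labels do not state that the numbers pair arrays, so the main fit leaves this shared variation in its spread. Of 100 same-numbered pairs 67 had r above 0.1, and in 0 of 10 pairs of groups did every number. The lowest r, −0.515, was between mp53 and Ras, whose arrays labelled 10 each resemble the other's group, so it says little about pairing. Blocking on the replicate numbers gave 7502 genes in mp53/Ras, 5091 in mp53, 5902 in Ras, 5388 in bleo/Neo against YAMC and 3616 non-additive. With this block 5 lists in place of 6 were called for the non-additive term. Without mp53 10 and Ras 10 the counts were 7117, 4710, 5606, 4997 and 3017, and without YAMC 2 and mp53 8 also, 7460, 5172, 6074, 5243 and 3341. Dcn in mp53, −0.88, was −0.57 without the 4 arrays, and Dusp6 in mp53, −0.66, was −1.02.

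Over all settings the changed genes ranged from 6072 to 9279 in mp53/Ras (13 settings), from 4556 to 7417 in Ras, from 4066 to 6756 in bleo/Neo against YAMC and from 5266 to 8121 in mp53/Ras against mp53, always within 1.5 times the reported count, as were the 661 to 970 genes changed 2-fold in mp53/Ras. They ranged from 2952 to 6714 in mp53, from 2209 to 4973 in mp53/Ras against Ras and from 1602 to 5137 for the non-additive term. Without a filter, non-additive genes numbered 5038 and genes of mp53/Ras against Ras 4576, since more genes were tested; 3072 of 3073 and 2778 of 2779 calls were kept. With array weights they numbered 5137 and 4973, and the cause was not tested. A limit of 0.8 left 761 genes on the linear scale, by its construction.

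Without mp53 10 and Ras 10 the mp53 lists went from 6 (5 higher, 1 lower) to 9 (5 and 4), and without 4 arrays to 8 (4 and 4). Lists called with an estimated correlation numbered 2 in mp53/Ras, 1 in mp53, 3 for the non-additive term and 0 in Ras (camera; 4 lists at an unadjusted p under 0.05), and with fry 20, 14, 13 and 15. With YAMC as the control 13, 3 and 3 lists were called in mp53/Ras, in mp53 and for the non-additive term. With YAMC 2952 genes changed in mp53, 1602 were non-additive and 145 at 2-fold; the cause was not tested beyond the difference between bleo/Neo and YAMC. The correlation of mp53 and Ras differences was 0.627 with the bleo/Neo arrays split and 0.493 with both against YAMC. It was −0.0511 with mp53 against bleo/Neo and Ras against YAMC. Those comparisons share no control, but the difference between bleo/Neo and YAMC enters the value, so it does not isolate the shared control.

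Of 231 named values, all kept their call (higher, lower or not passing) without a filter, 229 without 2 or 4 arrays and 227 with the block. Actb in mp53 (0.18 without 2 arrays, 0.21 without 4) and Vim in Ras (0.16 in both) passed, as they did with the block, where Vim in mp53 (0.15) passed too and Dusp6 in mp53 (−0.66) no longer did. With the mean of all probe sets 7 of 208 changed their call. Actb (0.05), Mdm2 (−0.08) and Plk2 (0.03) in mp53/Ras, Ccnd1 in mp53 (0.28) and Cdkn1a in Ras (−0.12) no longer passed, and Nras did in mp53/Ras (0.34) and Ras (0.20). With YAMC in place of bleo/Neo 118 of 170 kept their call, 23 kept only their direction and 29 changed sign, whether or not they passed against YAMC. In mp53 these were Zic1 −1.05, Mdm2 −0.22, Akr1c14 0.63, Bgn −0.35, Cdh11 −0.39, Col1a2 −0.24, Col8a1 −0.76, Dcn 0.56, Gpm6a 0.82, Mmp2 −0.39, Nid1 −1.21 and Slc16a3 0.31. In Ras they were Akr1c14 0.017, Mdm2 −0.19, Eif2s3y −0.10, Gpm6a 0.50, Rps4l −0.52, Slc16a3 1.04 and Zic1 −0.34, and in mp53/Ras Dhcr7 0.17, Eif2s3y −0.45, Gpm6a 0.99, Rps4l −0.74 and Zic1 −0.48. Non-additive terms that changed sign were Akr1c14 −0.41, Bgn 0.49, Col1a2 0.57, Gpm6a −0.34 and Zic1 0.91. Several values that changed sign did not pass against YAMC, for example Col1a2 in mp53 and Akr1c14, Eif2s3y and Zic1 in Ras. For those no opposite difference was shown. The cause of the changes of sign was not tested beyond the difference between bleo/Neo and YAMC.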

Other observations

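The relation of Xist to the Y-linked genes within groups was computed after the levels had been seen. Besides YAMC it gave r of 0.6 in bleo/Neo, −0.359 in mp53, −0.346 in Ras and −0.259 in mp53/Ras arrays, with p values of 0.07, 0.32, 0.33 and 0.48 (10 arrays each). Without the 2 arrays farthest out in Y-linked level these were −0.12, −0.398, −0.156 and −0.738, so a negative relation is not particular to YAMC. In 113 genes all 10 bleo/Neo arrays lay below the 40 others and in 81 above, 49 and 17 of them with means at least 4-fold apart. In mp53/Ras 189 genes lay below and 35 above, 14 and 3 at 4-fold. YAMC had 2 and 1, mp53 had 0 and 0, and Ras had 1 and 2. YAMC, mp53 and Ras each hold at least 1 array nearer another group, which by itself keeps their counts low. The counts of these groups therefore cannot be compared with those of bleo/Neo and mp53/Ras.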
